A study of Mus musculus with 2 samples.

How the data were processed

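Chromatin immunoprecipitation for H3K27me3 followed by sequencing was carried out on heart tissue of mouse embryos at day 12.5, with 2 biological replicates per the labels, which also give a fragment size range of 300 to 500 for the libraries. The files used here were 4 peak lists on mm10 in the narrowPeak format, per the deposited descriptions: 1 for each replicate, a pooled list and a replicated list. Per the same descriptions, each replicate's peaks were derived from its own alignment and 1 further file, and the pooled list from both alignments and both further files. The aligner, the peak caller and its settings, and the rule that made the replicated list are not given in the sources used here. Control libraries and alignments were not analysed here. The read depth of the libraries is unknown, so no interval that needs it was computed, and part of the difference in peak number between replicates could not be separated from depth.

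The deposited signal value of each peak was used to describe, rank or filter peaks and to compare gene sets by permutation in the closing section, each within 1 list, because the sources used here do not state whether it is a fold over a control. The deposited −log10 p and −log10 q of each peak were used to describe, rank or filter peaks within 1 list. The lowest −log10 p was about 2 in each list (2.02 in replicate 1 and 2.01 in replicate 2). The share of peaks with −log10 q of 2 or more was 70.2% in replicate 1, 65.6% in replicate 2, 80.5% in the pooled list and 97.6% in the replicated list. Peaks covered 59.5 Mb in replicate 1, 53.1 Mb in replicate 2, 88.4 Mb in the pooled list and 59.2 Mb in the replicated list. In replicate 1, 1 peak on an unplaced scaffold was left out. All replicated peaks were checked to be members of the pooled list, so the pooled and replicated lists are not independent of each other.

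Genes came from GENCODE release M21 and sequence from GRCm38, the assembly that mm10 names. The 21646 protein-coding genes on chromosomes 1 to 19 and X were tested. A gene was called marked when a peak overlapped, by at least 1 bp, the window from 1 kb upstream to 1 kb downstream of any annotated TSS of its protein-coding transcripts. Coverage was the percentage of the 10 kb window centred on the 5′ end of the gene that peaks covered in each replicate list, given as mean ± SD of both. Domains were replicated peaks merged over gaps of up to 3 kb. The CpG ratio was the observed over expected number of CpG dinucleotides in the promoter window at the 5′ end. Coverage and marking depend on where peaks were called: a narrow-peak format breaks broad regions of this mark into many short peaks, and weak enrichment under the calling threshold is counted as no mark.

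The 16 gene lists, the 28 individually chosen genes, the tests and most alternatives were fixed before the data were examined. The genes named from each list were the 3 marked members with the largest mean coverage and the first 2 unmarked members in list order. All marked or all unmarked members were named where they numbered 5 or fewer, and the 28 chosen genes were added. The other unmarked cardiac factors, the widest domains and the gene sharing a promoter window with Rpl3 were named after their values were seen.

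Each list was set against all other tested genes with a two-sided Fisher's exact test, adjusted by Benjamini-Hochberg over the 16 lists with a threshold of 0.05. Genes are the units of this test, so it describes these peak lists and not a spread between embryos. With 2 replicates in 1 group, no test between groups could be made. Lists were also tested against 10000 circular shifts of the marks along the gene order, which keep neighbouring genes together, and against 10000 random lists matched on promoter CpG ratio in 50 bins. Pairs of lists were compared by Fisher's exact test after leaving out shared genes. Overlap of peak lists and their share in promoters were set against 100 circular shifts along each chromosome, leaving out the first 3 Mb. The tests were tested on simulated data of 21646 genes, with lists of 30 genes drawn 200 times. Fisher's test called 2% of scattered unrelated lists, 25% of unrelated lists made of neighbouring genes and 97.5% of scattered lists with 50% of members marked. The circular shift called 1% of the unrelated lists of neighbours.

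Alternatives were −log10 q of at least 2, signal of at least 3, at least 500 bp of the window covered, windows of 500 bp and 2.5 kb on each side, the 5′ end of the gene only, the pooled list and each replicate list alone. Merge gaps of 1 and 10 kb, a coverage window of 4 kb and stricter overlaps between replicates were tried too. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.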

Results

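Trimethylation of lysine 27 of histone H3 (H3K27me3), the mark laid down by Polycomb repressive complex 2 on silenced developmental genes, was profiled by chromatin immunoprecipitation and sequencing in the heart of mouse embryos at embryonic day 12.5 (E12.5). The tissue came from strain B6NCrl, and embryos of both sexes were pooled. The data hold 1 group of 2 biological replicates, so they describe where the mark lay in this tissue and give no contrast between conditions. Peaks were listed for replicate 1 (141209 peaks), replicate 2 (126823 peaks), both together (the pooled list, 182501 peaks) and as a replicated list of 69493 peaks. The number of reads behind each library is unknown from these files, so no interval that depends on read depth is given. Replicate values are means ± SD with n = 2.

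The first question was which genes carried the mark at their promoters. Of 21646 protein-coding genes on chromosomes 1 to 19 and X, 4649 (21.5%) had a replicated peak within 1 kb of a transcription start site (TSS) and are called marked below. The share was 25.3% in the replicate 1 list and 23.7% in the replicate 2 list, a mean of 24.5% ± 1.14 (SD, n = 2). Both replicate lists marked 4421 genes, while 1048 were marked in replicate 1 only and 700 in replicate 2 only. Near-continuous marking was rare: 96 genes had at least 90% of the 10 kb around their 5′ end covered by peaks in both replicates, and the median gene had 0% of this window covered in each replicate.

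Most genes on 4 lists of developmental regulators and on the list of signalling genes were marked. All 39 Hox genes, which set position along the body axis, were marked, and so were 67 of 68 transcription factors of neural development (98.5%). The corresponding shares were 85.7% of 28 endoderm transcription factors, 78.6% of 42 transcription factors of skeletal muscle and other mesoderm, and 93.0% of 57 signalling ligands and antagonists. Between 21.2% and 21.4% of the genes outside each of these lists were marked. By two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 16 lists, the adjusted p was 4.17e-26 for Hox genes, 1.03e-42 for neural factors and 1.93e-12 for endoderm factors. It was 1.46e-14 for the mesoderm factors and 3.86e-30 for the signalling genes. In each replicate list alone, at least 83.3% of each of these lists was marked.

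Among the Hox genes, Hoxb5 had 99.0% ± 1.45 (SD, n = 2) of its 10 kb window covered, Hoxc12 97.4% ± 1.68 and Hoxc4 96.6% ± 0.255. Hoxa13 and Hoxd13, at the 5′ ends of their clusters, had 77.3% ± 3.16 and 80.0% ± 0.177, and Hoxb1, at a 3′ end, had 83.9% ± 7.04. The neural regulators Neurog1 (99.6% ± 0.530), Olig2 (99.0% ± 0.0424) and Six3 (97.7% ± 0.877) were covered almost throughout. Pax6, a regulator of eye and brain development, had 91.2% ± 2.60. Neurod4 was the only neural factor without a replicated promoter peak, with 0.940% ± 1.33 covered. Neurog1 lies at 56250478 to 56252163 on chromosome 13 (mm10), and the replicated peak over its TSS spanned 56245789 to 56257936.

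Endoderm regulators followed the same pattern, with 98.8% ± 0.841 (SD, n = 2) of the window covered at Neurog3, the pancreatic endocrine determinant, 95.7% ± 1.53 at the intestinal factor Cdx2 and 95.1% ± 1.61 at the liver and pancreas factor Onecut1. Pdx1, required for pancreas formation, had 89.5% ± 2.43. The unmarked members were Hnf4g, Isx, Prox1 and Gata4, of which Prox1 and Gata4 are also on the list of cardiac transcription factors. In the mesoderm list the muscle progenitor factor Pax7 (95.6% ± 3.69), brachyury (gene symbol T, 93.6% ± 5.69) and the myogenic determinant Myod1 (91.8% ± 2.06) had the largest coverage among marked members. Myf5 (2.82% ± 1.08) and Myf6 (0.985% ± 1.39), myogenic factors of the same family as Myod1, had no replicated promoter peak. Of the signalling genes, Wnt10a (98.6% ± 0.891), Wnt7a (95.1% ± 0.651) and Wnt10b (93.5% ± 0.467) led, with 89.95% ± 4.44 at Shh and 79.9% ± 0.983 at Wnt1. The 4 unmarked signalling genes were Wnt5a, Bmp5, Inha and Cer1.

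**Figure D1:**
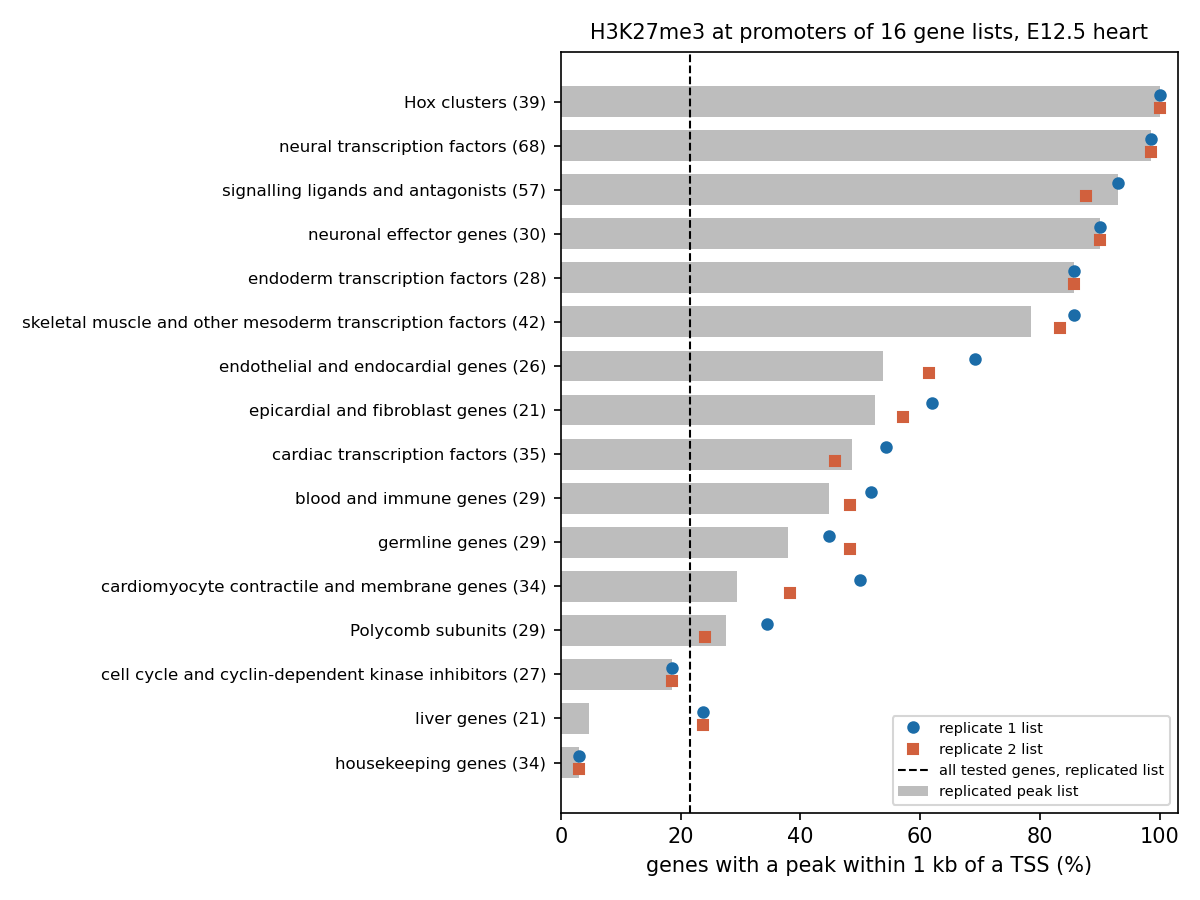
Share of genes with an H3K27me3 peak within 1 kb of a TSS (x axis, %) in 16 gene lists (y axis, number of genes in parentheses); bars show the replicated list, circles replicate 1, squares replicate 2, and the dashed line all tested genes (21.5%). Hox genes (100%) and neural transcription factors (98.5%) stand at the top, and housekeeping genes (2.94%) at the bottom.

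Genes of the heart itself were divided. Of 35 cardiac transcription factors, 17 were marked (48.6%), against 21.4% of other genes (Fisher's exact test, adjusted p = 0.00111), with 54.3% in replicate 1 and 45.7% in replicate 2. The marked members with the largest coverage were Tbx1, a factor of the pharyngeal arches and second heart field (86.4% ± 4.53, SD, n = 2), Irx6 (79.4% ± 4.36) and Pitx2, which sets left-right asymmetry (70.0% ± 1.76). Isl1, a marker of second heart field progenitors, had 45.4% ± 0.764 of its window covered, and 18.99% with a 4 kb window. Nkx2-5, an early cardiac determinant, had 37.0% ± 18.4, with 50.04% in replicate 1 and 24.0% in replicate 2. Tbx5 was marked by the replicated list through 276 bp of its promoter window, had no promoter peak in replicate 2, and had 7.81% ± 8.27 of the window covered.

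Other core cardiac regulators had no replicated promoter peak. Gata4, Gata5 and Hand2 had 0% of the 10 kb window covered in either replicate. The remaining unmarked cardiac factors included Gata6, Tbx20, Mef2c, Srf and Myocd. Unmarked refers here to the replicated list, and the pooled list marked 57.1% of the cardiac factors. Cardiac transcription factors were marked less often than neural ones. Leaving out 1 gene on both lists, 16 of 34 cardiac factors (47.1%) and 66 of 67 neural factors (98.5%) were marked, a difference of -51.4 percentage points (odds ratio 0.0142, 95% interval 0.000319 to 0.102, two-sided Fisher's exact test p = 9.17e-10, with 3 such comparisons of lists made). The difference kept its sign in each replicate list taken alone, at -45.6 points in replicate 1 and -54.4 points in replicate 2.

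Genes of the cardiomyocyte contractile apparatus and membrane were marked in 10 of 34 cases (29.4%), against 21.5% of other genes, and did not pass the test (Fisher's exact test, adjusted p = 0.336). The ion channel genes Scn5a (73.9% ± 13.4, SD, n = 2), Kcnq1 (43.1% ± 7.13) and Hcn4 (32.8% ± 5.54), which act in cardiac conduction and pacemaking, had the largest coverage. Myh7, the slow myosin heavy chain, had 21.2% ± 2.60, and Nppa, the atrial natriuretic peptide gene, 15.5% ± 2.45 (26.8% with a 4 kb window). The sarcomere genes Myh6 (1.75% ± 2.47), Tnnt2 (1.80% ± 2.55) and Actc1 (2.01% ± 2.84) had short peaks in replicate 1 and none in replicate 2, and no replicated promoter peak. With a 4 kb window these values were 0%, 0% and 5.01%. Myl3, a ventricular light chain gene, had no replicated promoter peak either, with 13.0% ± 5.55. This list was sensitive to the choice of peaks: 50% was marked in replicate 1 alone (adjusted p = 0.00302), 38.2% in replicate 2 alone and 52.9% in the pooled list (adjusted p = 0.00426), all by Fisher's exact test. With replicated peaks of signal 3 or more it was 14.7%, and 18 of the 27 marked genes of both cardiac lists then stayed marked. The share was 19.2 percentage points lower than that of cardiac transcription factors in the replicated list, which did not pass Fisher's exact test (p = 0.140), and the gap was 4.29 points in replicate 1 and 7.48 points in replicate 2.

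Markers of the other cell types of the heart were marked more often than other genes. The share was 53.8% of 26 endothelial and endocardial genes (adjusted p = 0.000677), 52.4% of 21 epicardial and fibroblast genes (adjusted p = 0.00319) and 44.8% of 29 blood and immune genes (adjusted p = 0.00776), all by Fisher's exact test. Among endothelial genes the Notch ligand gene Dll4 (90.2% ± 2.79, SD, n = 2), Sox7 (82.3% ± 3.87) and Sox18 (66.7% ± 1.98) were covered most. The adhesion molecule genes Pecam1 (0%) and Cdh5 (2.28% ± 0.559) had no replicated promoter peak. Wt1, an epicardial transcription factor gene, had 73.8% ± 6.24, and the fibroblast genes Col1a1 and Thy1 had 50.5% ± 12.1 and 49.99% ± 5.76. Of the epicardial genes Tbx18 and Upk3b, neither had a replicated promoter peak, and 30.7% ± 6.29 and 0% of their 10 kb windows were covered. For Tbx18 it was 18.0% with a 4 kb window. In the blood list the hematopoietic factor genes Gata2 (86.0% ± 2.26), Gfi1 (77.9% ± 2.23) and Runx1 (67.3% ± 1.08) led. The erythroid factor gene Gata1 (0%), the myeloid factor gene Spi1 (1.895% ± 2.68) and the alpha-globin gene Hba-a1 (33.3% ± 7.37, and 11.4% with a 4 kb window) had no replicated promoter peak.

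Of the terminal genes of other organs, neuronal effectors were marked more often than other genes and liver genes did not pass the test. Of 30 neuronal effector genes, 27 were marked (90%, Fisher's exact test, adjusted p = 7.04e-15). Slc32a1, the vesicular transporter of inhibitory transmitters (97.7% ± 2.55, SD, n = 2), Chat, which makes acetylcholine (82.1% ± 4.19), and the potassium channel gene Kcnc1 (82.1% ± 4.84) led this list. Snap25, Elavl4 and Vip were unmarked. The share of neural transcription factors was 8.53 percentage points higher than that of neuronal effectors (Fisher's exact test p = 0.0840). That gap passed the threshold in 4 other settings, for example at 17.1 points with peaks of signal 3 or more (Fisher's exact test p = 0.00951). Of 21 liver genes, only Rbp4, the retinol carrier gene, was marked (4.76%, Fisher's exact test, adjusted p = 0.0795). Alb and Afp, the albumin and alpha-fetoprotein genes, had 0% and 1.87% ± 0.0849 covered. In each replicate list 5 of the 21 liver genes (23.8%) were marked, close to the share of all genes in these lists.

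Housekeeping genes were nearly free of the mark, with 1 of 34 marked (2.94%, Fisher's exact test, adjusted p = 0.00776) in the replicated list and in each replicate list. Actb and Gapdh had 0% of the window covered in both replicates. The marked member was the ribosomal protein gene Rpl3 (36.8% ± 0.658, SD, n = 2), whose promoter window also holds a TSS of Syngr1, a synaptic vesicle protein gene. Polycomb subunit genes (8 of 29, 27.6%, adjusted p = 0.529) and genes of the cell cycle and its inhibitors (5 of 27, 18.5%, adjusted p = 0.819) did not pass Fisher's exact test. Cbx8 (64.7% ± 5.18), Pcgf1 (52.2% ± 5.47) and Cbx4 (50.4% ± 1.61) were the Polycomb genes with the largest coverage, while the methyltransferase genes Ezh1 and Ezh2 were unmarked. In the cell cycle list the marked genes were the inhibitor genes Cdkn1a, Cdkn2a, Cdkn2b and Cdkn2c and the germ cell cyclin gene Ccna1. Cdkn2a had 71.9% ± 1.05 of its window covered, Ccna1 45.8% ± 0.346 and Cdkn2b 44.6% ± 4.00, while Cdkn1b (0%) and Cdkn1c (10.9% ± 0.0566) were unmarked.

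Germline and pluripotency genes were marked in 11 of 29 cases (37.9%, Fisher's exact test, adjusted p = 0.0537). The pluripotency factor genes Pou5f1 (70.4% ± 2.02, SD, n = 2) and Nanog (24.4% ± 0.297) and the protamine gene Prm2 (45.4% ± 3.52) had the largest coverage among marked members. Ddx4 and Dazl, germ cell RNA-binding protein genes, were unmarked. The share passed the threshold in both replicate lists taken alone, at 44.8% in replicate 1 (adjusted p = 0.0362) and 48.3% in replicate 2 (adjusted p = 0.00535), by Fisher's exact test. Of the 12 alternatives run on this list, 4 passed it and 8 did not. Among the 8 was the 5′ end of the gene only (27.6%, Fisher's exact test, adjusted p = 0.303). The test treats genes as the units and neighbouring genes are not independent. With the marks shifted around the gene order, and against random lists matched on promoter CpG ratio, all 16 lists kept their side of the 0.05 threshold.

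**Figure D2:**
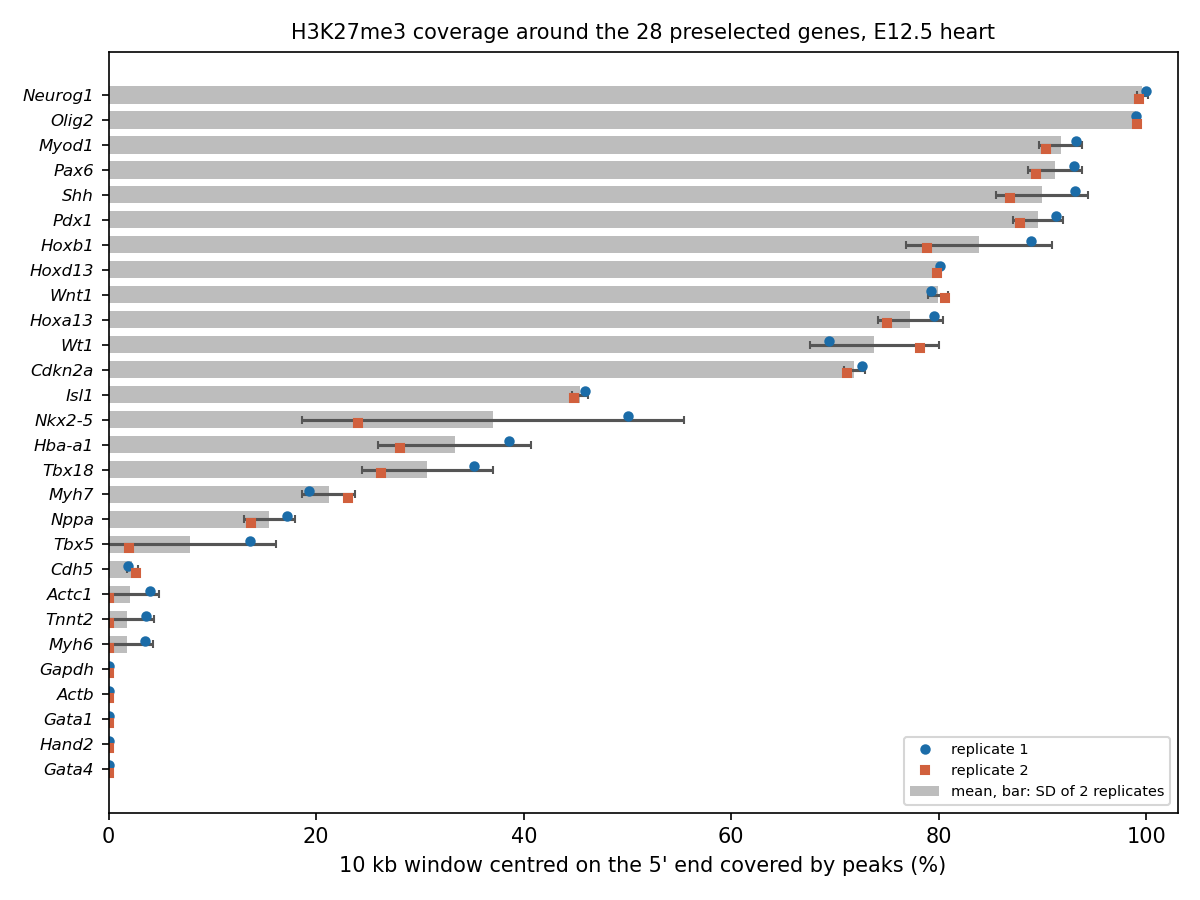
Share of the 10 kb window centred on the 5′ end that was covered by H3K27me3 peaks (x axis, %) for 28 genes chosen before the data were examined (y axis); bars are means of both replicates with SD, circles replicate 1 and squares replicate 2. Neurog1 (99.6%) and Olig2 (99.0%) lie at the top, Nkx2-5 (37.0%) in the middle with the widest spread, and Gata4, Hand2, Gata1, Actb and Gapdh at 0%.

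The 4 Hox clusters were among the 10 widest stretches of the mark. Replicated peaks closer than 3 kb were merged into 22558 domains with a median width of 1094 bp. Only 2276 were at least 10 kb wide, and these held 55.2% of all domain length. Of the widest class, 124 reached 50 kb and 18 reached 100 kb. The 5′ end of a protein-coding gene lay in 8.65% of domains under 10 kb. It lay in 51.3% of those of at least 10 kb and in 80.6% of those of at least 50 kb. A wider domain is more likely to hold a 5′ end by its width alone, and no expectation for width was computed. Other annotated TSS were not counted here.

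The widest domain (290 kb) covered the HoxC cluster at 102871936 to 103161585 on chromosome 15, with 9 Hox genes. Peaks of each replicate covered 80.9% ± 0.697 (SD, n = 2) of it. The HoxB cluster followed (217 kb, chromosome 11, 96227379 to 96444097), and the HoxA cluster with Evx1 (192 kb, chromosome 6, 52139398 to 52331653) and the HoxD cluster with Evx2 (136 kb, chromosome 2, 74643356 to 74779433) were also among the 10 widest. Single transcription factor genes lay in domains about as wide as that of HoxD and narrower than those of the other clusters: Pax2 (145 kb, chromosome 19, 44710800 to 44856061), Sox1 (135 kb, chromosome 8, 12379148 to 12514512) and Pax7 (126 kb, chromosome 4, 139738840 to 139864711). The third widest (213 kb, chromosome 2, 165062193 to 165275366) held the TSS of the cadherin gene Cdh22 and of 1700025C18Rik. A domain on chromosome 4 (168 kb, 136817336 to 136985004) held the ephrin receptor genes Ephb2 and Epha8 with the complement genes C1qa, C1qb and C1qc between them. Others held the TSS of Rhcg, an ammonium transporter gene (151 kb, chromosome 7, 79483399 to 79634585), of Sipa1l3 (147 kb, chromosome 7, 29377415 to 29524895), and of Faim2 with the aquaporin genes Aqp2, Aqp5 and Aqp6 (127 kb, chromosome 15, 99483295 to 99610390). The number of domains depended on the merging distance and on the list, and with a gap of 10 kb the widest domain (536 kb) held 0 Hox genes. In the replicate 2 list alone the widest was the HoxB domain (324 kb, with 10 Hox genes).

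**Figure D3:**
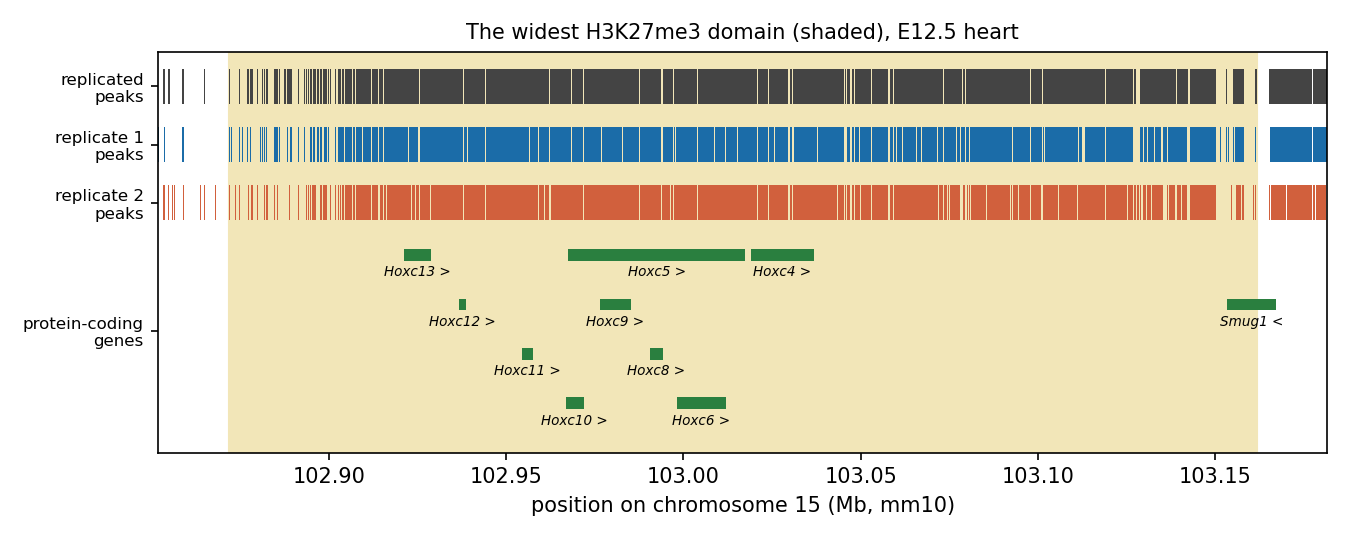
Map of the widest H3K27me3 domain (shaded) on chromosome 15 (x axis, position in Mb, mm10), with replicated, replicate 1 and replicate 2 peaks as blocks and protein-coding genes drawn to scale with their direction. The 290 kb domain holds the TSS of 9 HoxC genes and peaks of each replicate cover 80.9% ± 0.697 of it.

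The mark was concentrated at promoters relative to chance placement. Promoter windows (within 1 kb of a TSS) took up 11.2% of replicated peak length, against a mean of 2.70% in 100 circular shifts of the peaks along each chromosome, a ratio of 4.17. Exons outside promoters took up 6.23% (ratio 2.44), introns 36.6% (ratio 1.01) and intergenic DNA 45.9% (ratio 0.785). The promoter share was 10.5% ± 0.102 (SD, n = 2) in the replicate lists. The one-sided permutation p for promoters, exons and intergenic DNA was 0.0099, the smallest that 100 shifts can give, and that for introns was 0.386.

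Promoters of middling CpG content were marked most often. Genes were ranked by the observed over expected CpG ratio of their promoter and divided into 10 groups of equal size. The marked share was 4.94% in the lowest group, 36.3% in group 5 and 13.7% in the highest. The replicate means were 7.60% ± 1.14, 39.0% ± 1.44 and 14.3% ± 1.01 (SD, n = 2). Because the relation rose and then fell, Spearman's rho across genes was only 0.0394 in the replicated list, and genes are not independent replicates. It was 0.00714 in replicate 1, 0.0103 in replicate 2 and -0.0137 in the pooled list, so its sign depended on the list. Genes with near-continuous peaks were found at higher CpG ratios, with 20 in group 8, 19 in group 9 and 16 in the highest, and 0 in the lowest.

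**Figure D4:**
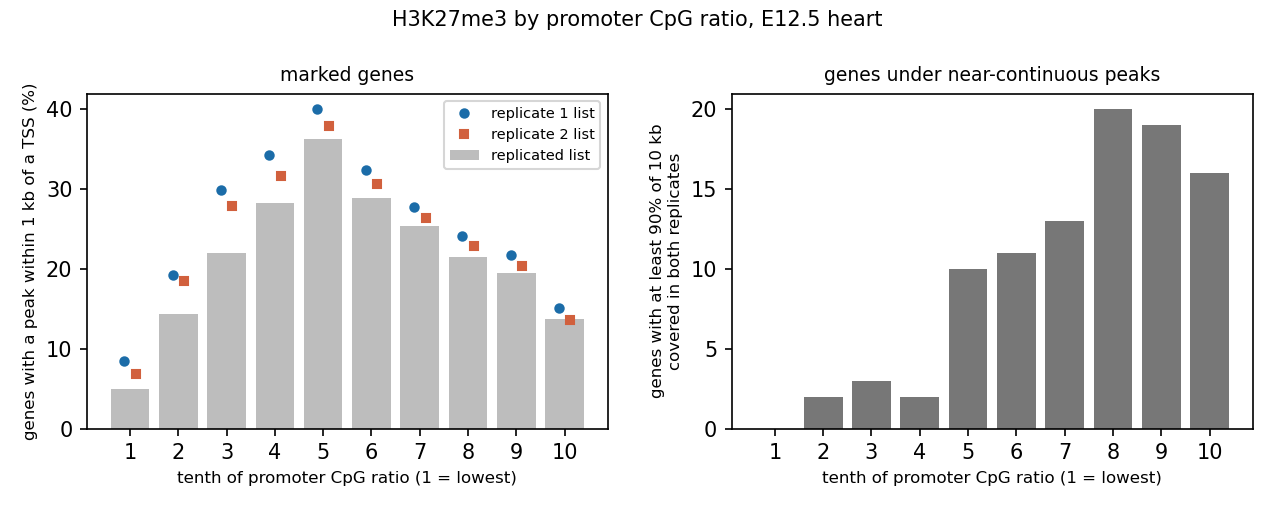
Left, share of genes with a peak within 1 kb of a TSS (y axis, %) in 10 equal groups of genes by promoter CpG ratio (x axis, 1 lowest), with bars for the replicated list, circles for replicate 1 and squares for replicate 2; right, number of genes with at least 90% of the 10 kb window covered in both replicates. The marked share peaks at 36.3% in group 5, and near-continuous coverage is most frequent in group 8 (20 genes).

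Chromosomes differed in how much of them was marked. Peaks covered 38.0 ± 3.48 kb per Mb (SD, n = 2) on chromosome 11, 33.8 ± 2.44 on chromosome 19 and 31.8 ± 3.08 on chromosome 4. The lowest values were 10.6 ± 1.05 on the X chromosome and 10.7 ± 0.233 on chromosome 3. Their order depended on the list. Chromosome 3 was the lower in the replicated list (10.6 against 11.5) and in replicate 1 (10.9 against 11.4), and the X chromosome in replicate 2 (9.89 against 10.6). These values were not corrected for gene density, which ran from 5.34 tested genes per Mb on chromosome 12 to 13.8 on chromosome 7. The X chromosome had 0.503 of the median autosomal value in the replicated list, 0.490 in replicate 1 and 0.489 in replicate 2. Embryos of both sexes were pooled, and these ratios were not corrected for the number of X chromosomes. The share of marked genes on the X chromosome was 21.5%, while among the autosomes it ran from 16.04% on chromosome 14 to 31.3% on chromosome 15.

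The replicates shared far more peaks than chance placement gave. Of the replicate 1 peaks, 46.2% overlapped a replicate 2 peak by at least 1 bp, and of the replicate 2 peaks, 53.1% overlapped replicate 1. Circular shifts gave 3.91% ± 0.278 and 4.35% ± 0.311 (SD over 100 shifts), with a permutation p of 0.0099 in each direction, the smallest they can give. Overlap was highest among strong peaks, which were also wider. With the replicate 1 peaks divided into 5 equal groups by −log10 p, 83.0% of the strongest group overlapped replicate 2, against 29.1% of the weakest. The corresponding shares for replicate 2 were 88.1% and 33.8%. Median width was 583 bp in the strongest and 214 bp in the weakest group of replicate 1, and 579 and 216 bp in replicate 2. When only the summit of each peak was counted, so that its own width did not matter, the shares were 70.6% and 20.02% in replicate 1 and 78.4% and 24.0% in replicate 2.

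The replicated list kept the wider and stronger part of the pooled list. All 69493 replicated peaks were also in the pooled list, and they made up 38.1% of its peaks and 67.0% of its covered length. Median width was 526 bp for kept peaks and 229 bp for the others, and median signal was 2.85 and 2.23. Of the kept peaks 74.4% overlapped a peak in both replicate lists, and of those not kept 0.948% did.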

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

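The alternatives were chosen before the data were examined, except the replicated peaks that overlap both replicate lists, the CpG relation with stricter peaks and the overlap by summits. Of the 192 alternatives run on the 16 gene lists, 182 kept both the direction and the side of the threshold, and 12 lists kept them under all 12 alternatives run on each. These counts include −log10 q of at least 2, which could hardly change a call because 99.5% of marked genes stayed marked. Cardiac against neural transcription factors and the promoter enrichment kept their direction and call under all alternatives run on them. The overlap between replicates stayed above that of the shifts, but fell to 22.6% of replicate 1 peaks and 25.2% of replicate 2 peaks when at least 50% of both peaks had to overlap (20 shifts), and to 34.9% and 41.8% by summits. The number of marked genes ran from 3440 (signal of at least 3) to 6172 (pooled list). The direction turned for contractile genes with signal of at least 3 (14.7%, against 15.9% of other genes), for Polycomb subunits with the 5′ end only (17.2%, against 19.4%), and for liver genes with the pooled list (28.6%) and without replicate 1 (23.8%, also the value without replicate 2). None of these passed the threshold before or after. Contractile genes passed it with the pooled list (52.9%) and without replicate 2, with 38.2% to 50% when each replicate was left out. Germline genes passed it with the 500 bp window (34.5%), the pooled list (65.5%) and each replicate left out (44.8% to 48.3%). Neural transcription factors exceeded neuronal effectors past the threshold with signal of at least 3 (17.1 points), with 500 bp of the window covered (15.2 points), and with the 500 bp window and the 5′ end only (11.9 points each). The cause was not tested. The replicated list kept 46.1% of pooled peaks with −log10 q of at least 2. There were 34357 domains with a 1 kb gap and 13635 with a 10 kb gap, as the gap itself dictates, 47317 with the pooled list and 40765 to 42021 with each replicate left out. Spearman's rho with promoter CpG ratio was 0.0562 with the 5′ end only, -0.0137 with the pooled list, 0.00714 to 0.0103 with each replicate left out and 0.0746 with signal of at least 3. The X chromosome ratio was 0.504 with −log10 q of at least 2. Coverage of 17 of the 28 chosen genes moved by more than 1 SD with a 4 kb window, by over 1.5 times at Isl1 (18.99%), Hba-a1 (11.4%), Tbx18 (18.0%), Nppa (26.8%) and Actc1 (5.01%), and Myh6 and Tnnt2 went to 0% within their SD. No paired analysis was possible because there is 1 group. Read depth is unknown, so a gene without a peak may have been under the calling threshold: the pooled list marked 6172 genes.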

Other observations

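The tests of signal at cardiac genes, the tests of symbol families and the description of the strongest peaks were chosen after the results were seen, and those of split domains and of summits after the overlap by peak strength was seen. Gene families defined by symbol, some with members on the chosen lists, also differed in the mark. Genes were grouped by the leading letters of their symbols, and 111 families had at least 20 tested members. By Fisher's exact test with Benjamini-Hochberg adjustment over these families, 13 had a higher and 24 a lower marked share than other genes, and 11 and 13 did when the marks were shifted along the gene order. Fibroblast growth factor genes (Fgf, 18 of 22, 81.8%, adjusted p = 4.32e-08), keratin genes (Krt, 33 of 53, 62.3%, adjusted p = 3.59e-09), semaphorin genes (Sema, 12 of 20, 60%, adjusted p = 0.00165) and collagen genes (Col, 24 of 45, 53.3%, adjusted p = 3.38e-05) lay on the high side by this exact test. Solute carriers (Slc, 131 of 371, 35.3%, adjusted p = 1.17e-08, exact test) did too. Members on the chosen lists numbered 10 for Fgf, 2 for Krt, 0 for Sema, 3 for Col and 7 for Slc. Without them the marked shares were 66.7% for Fgf, 60.8% for Krt, 54.8% for Col and 34.1% for Slc, and these were not tested. The keratin share was 79.2% in replicate 1 and 60.4% in replicate 2.

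At the other end, olfactory receptor genes (Olfr, 29 of 1133, 2.56%, adjusted p = 4.40e-79), vomeronasal receptor genes (Vmn, 0 of 330, adjusted p = 5.71e-34) and zinc finger genes (Zfp, 32 of 394, 8.12%, adjusted p = 2.30e-11) were seldom marked by the same exact test. So were mitochondrial ribosomal protein genes (Mrpl, 0 of 49, adjusted p = 0.000121, exact test). Members of a family can be neighbours, which the exact test ignores. With the marks shifted along the gene order, the adjusted p was 0.00202 for each family named in this and the preceding paragraph. Promoter CpG ratio was not matched in the tests of families. The strongest replicated peaks by signal did not always lie at the 5′ end of a gene. Other annotated TSS of the genes were not checked for these peaks. The highest (signal 14.6, 12.1 kb, chromosome 11, 118566235 to 118578299) lay in an intron of the neuronal splicing factor gene Rbfox3, 92.7 kb from the nearest 5′ end of a protein-coding gene. Next came a peak that spanned the TSS of Neurog3 (signal 12.2), with its summit 3.82 kb away in an intron of Fam241b. After it came a peak with its summit in intergenic DNA 33.8 kb from Gsx1 (signal 11.5). Of the 15 widest domains, 2 held no 5′ end of a protein-coding gene, and other annotated TSS were not counted. The first (120 kb, chromosome 9, 61248407 to 61368377) ended 3.99 kb from the 5′ end of Tle3, and the second (117 kb, chromosome 14, 117907200 to 118023852) lay 28.4 kb from that of Dct. The second domain overlapped the genes Gpc6 and Dct themselves.

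Developmental regulators and signalling genes were marked more often than other genes. Most of them are known from other lineages, but some also act in the heart (Bmp10, for example, and the unmarked Gata4 and Prox1). In total, 216 of the 234 genes on the 5 regulator lists (Hox, neural, endoderm, mesoderm and signalling) were marked (92.3%). The promoter CpG ratio is argued against as the whole cause, since the highest of 10000 lists matched on it reached 31.6%. Only the ratio at the 5′ end was matched, so other measures of CpG content stay open. Chance alignment of neighbouring genes with clustered marks is argued against too, since the highest of 10000 shifts of the marks along the gene order reached 38.0%. The shifts cannot tell whether neighbours, such as the 9 HoxC genes of the widest domain, were marked through 1 shared domain. No biological explanation was tested, because the design has 1 group and no expression data were analysed here.

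Cardiac genes were marked in heart tissue, 27 over both cardiac lists. A mark of another protein-coding promoter within 1 kb is argued against. Of the 27, 81.5% were marked at their own 5′ end with no TSS of another protein-coding gene in the window. A domain that reaches the window from a promoter farther away was not tested, and neither were promoters of non-coding genes. Weak peaks stay open. With −log10 q of at least 2, 100% of the 27 stayed marked, which decides nothing because 99.5% of all marked genes did, and with signal of at least 3 it was 66.7%, against 74.0% of all marked genes and 98.5% of marked neural transcription factors. A mark present in only part of the cells stays open too. The median signal at marked cardiac genes was lower than at marked neural transcription factors, by -1.90 in replicate 1 (permutation p = 0.00402) and -1.36 in replicate 2 (permutation p = 0.00093). But neural factors are a heavily marked list, with a median coverage of 79.6%. A lower signal beside them therefore decides nothing about a mark in part of the cells. Weak peaks or a lower level of the mark in every cell would give the same values.

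Many peaks were called in 1 replicate only, since 46.2% of replicate 1 peaks and 53.1% of replicate 2 peaks were shared. Weak peaks near the calling threshold go with the rise of overlap with peak strength, which was also seen by summits (20.02% in the weakest and 70.6% in the strongest group of replicate 1), though peak width rose with strength. But in the strongest of 5 equal groups of replicate 1 peaks no more than 83.0% overlapped replicate 2, so this explanation stays open as the whole cause. The unshared peaks of this group lay near peaks of the other replicate, with 84.7% of the 4791 in replicate 1 and 86.9% of the 3015 in replicate 2 within 3 kb. This decides nothing about domains split at different places, because the lists lie together beyond chance whether or not domains were split. Unequal read depth could not be tested, since read counts were not analysed here.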
